A study of Mus musculus with 7 samples.

How the data were processed

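Total RNA from the left lungs of 8-week-old mice was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per mouse. The labels give 3 mice with a Gata5 deletion (KO) and 4 wild-type mice (WT) and call the samples of each group biological replicates. Groups and replicate numbers were taken from the labels alone. The allele's deleted exons are not given in the sources used here.

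The deposited table holds log2 levels of 45101 probe sets in 7 columns, each matched to its array by name. Affymetrix Expression Console, RMA and MAS5 are named per the submitters' processing notes, without versions or roles, so which method made the table is unstated. The range of the values and their near-equal distributions on all arrays are what RMA gives, and the log base was taken from that range. Values were used as deposited, to 2 decimals. Of 45037 probe sets that are not controls, the platform annotation gave 1 gene for 34945, several genes for 932 and none for 9160. Names were updated by gene identifier for 34741 probe sets from a RefSeq gene table of the mouse assembly GRCm38.p6, which was also used for gene order and gene type. No gene was named from a probe set with several genes.

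Each of 18193 genes was represented by its probe set with the highest mean over the 7 arrays. Genes with a mean at or above the 40th percentile of all probe set means, a log2 level of 5.47, were tested, which left 13285 genes and set aside 4908. KO and WT were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and adjusted p under 0.05 was the threshold. A second count took unadjusted p under 0.01 and a change of at least 1.5-fold. Gata5 lies under the level filter and was tested in the same fit run on all probe sets. Single values per array were compared with an exact two-sided permutation test over the 35 ways of splitting the 7 arrays into 3 and 4. Intervals are at 95%. For arrays, no counting depth applies, and their number limits the precision.

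Lists of genes for lung cell types, pathways and neighbouring tissues were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Of 41 lists, 40 had the 3 tested members required, and 553 of 600 members were on the array. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Genes next to Gata5 were up to 200 annotated genes on each side, fewer where the chromosome ended. Tested ones lay up to 197 genes away on 1 side and up to 72 on the other. They were compared with all other tested genes by Fisher's exact test, two-sided.

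The groups, the tests, the lists and the rule for naming genes were fixed before the data were examined. Named genes were Gata1 to Gata6, the 10 largest increases and the 10 largest decreases among changed genes whose groups did not overlap, the 4 members with the smallest p of each list that passed, the 2 brightest members of each list used as a check on other cell types, and up to 5 changed neighbours of Gata5. Further list members are named where few passed, and these and the control probe sets were chosen after their values were seen. Heat-shock and platelet genes outside the lists were drawn up after the results of those lists and before their own values were seen, and the ones named were picked afterwards.

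The fit was tested on simulated arrays of 3 and 4 with 13285 genes. It recovered 58 of 65 genes planted with a log2 change of 0.5, 68 of 69 at 1 and 65 of 66 at 1.5, with 11 false calls among 202. With nothing changed it made 0 calls. The simulated genes varied independently of each other and the simulated arrays did not differ in quality, so these rates need not hold for the real arrays. Alternatives covered the normalization between arrays, the level filter, the choice of probe sets, the variance model, array weights, the Xist level or a control index as a covariate, the replicate number as a block, the 5 mice with the lowest mouse numbers alone, and leaving out each array in turn. A change of pseudocount was not applied because the values were already on a log2 scale. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.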

Results

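Lung transcripts were measured after deletion of Gata5, which encodes a zinc-finger transcription factor of the GATA family. Left lungs came from 3 KO and 4 WT mice at 8 weeks of age, and each lung was profiled on 1 array. The median log2 level per array lay between 6.10 and 6.15. The first principal component of the tested genes held 47.7% of the variance and placed the 3 KO arrays apart from the 4 WT arrays. WT replicate 4 differed from the other arrays in sex-linked transcripts: Xist, the RNA that silences an X chromosome in females, stood at 11.51 against 3.66 to 3.89, and the Y-linked Eif2s3y at 3.71 against 9.30 to 9.68. The control probe sets also differed between the groups. The beta-actin 3′ probe set exceeded the 5′ probe set by a log2 difference of 4.96 ± 0.37 (SD, n = 3) on KO arrays and 4.10 ± 0.22 (SD, n = 4) on WT arrays, with no overlap (exact permutation p = 0.0286, the smallest that 35 splits can give). The Gapdh 3′ probe set exceeded the middle one by 4.01 ± 0.26 on KO arrays and 3.47 ± 0.16 on WT arrays (exact permutation p = 0.0286).

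**Figure D1:**
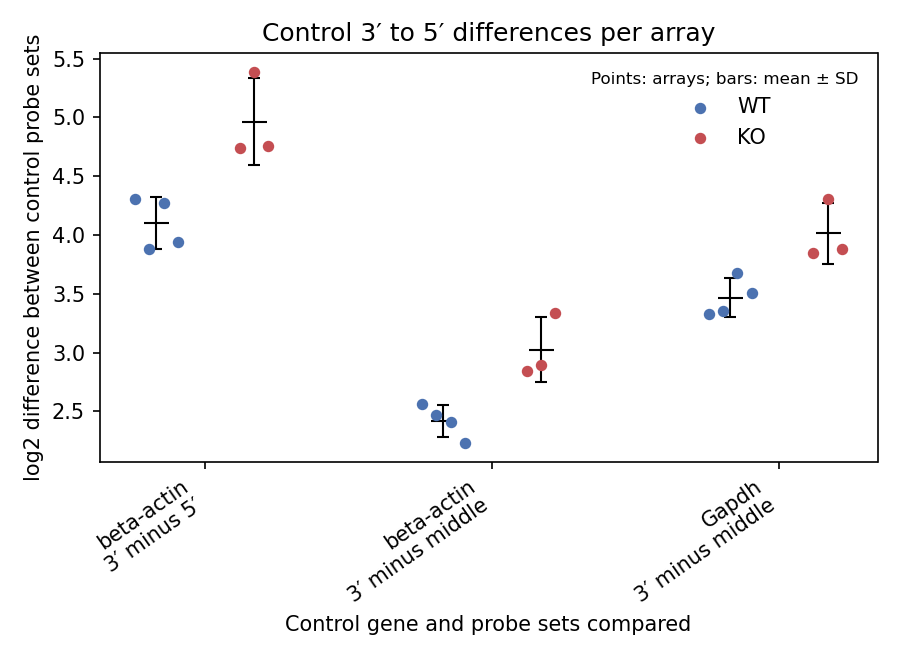
Log2 difference between 3′ and 5′ or middle control probe sets of beta-actin and Gapdh on each array, with points for arrays and bars for mean ± SD. The 3 KO arrays lie above the 4 WT arrays for each control.

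The targeted gene was examined first. Gata5 signal at probe set 1450126_at was 4.95 ± 0.22 (SD, n = 3) in KO and 5.54 ± 0.22 (SD, n = 4) in WT lungs, 1.51-fold lower in KO, and all 3 KO arrays lay below all 4 WT arrays (limma adjusted p = 0.0336). At the second Gata5 probe set, 1450125_at, the levels were 4.68 ± 0.19 in KO and 4.94 ± 0.06 in WT, again without overlap, but the change did not pass (log2 change -0.26, limma adjusted p = 0.0993). Among the other GATA factors, none passed: Gata1, an erythroid and megakaryocyte factor, differed by a log2 change of 0.22 (adjusted p = 0.121), Gata6, a factor of lung epithelium, by -0.27 (adjusted p = 0.167), Gata3 by -0.17, Gata4 by 0.04 and Gata2 by 0.01, the last 2 with a sign that another scaling turned, and Gata6 and Gata3 with one that the beta-actin 3′ minus middle difference as covariate turned (0.20 and 0.024). Zfpm2, a Friend of GATA cofactor, fell 2.02-fold, from 6.94 ± 0.18 to 5.92 ± 0.47 (adjusted p = 0.0156), and was the only 1 of the 7 tested members of the GATA list to pass, 1 also when adjusted over the list alone; its call was lost without KO replicate 3 (adjusted p = 0.0553). The list as a whole did not pass (camera adjusted p = 0.749). Both Gata5 probe sets were dim, and the call at 1450126_at was lost without KO replicate 1, KO replicate 2, WT replicate 2, WT replicate 3 or WT replicate 4, with a log2 change between -0.62 and -0.48 and adjusted p between 0.0606 and 0.0791. A probe set outside the deleted exons checks nothing, and which part was deleted is not given in the sources used here.

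**Figure D2:**
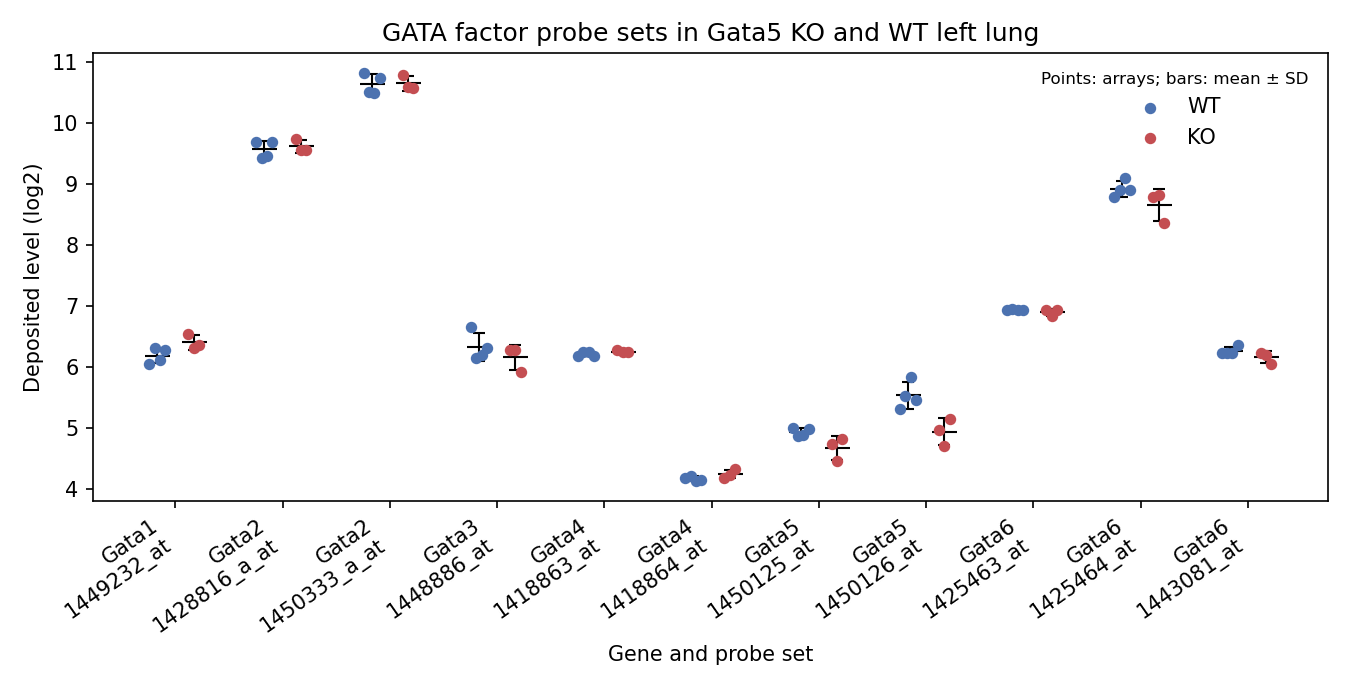
Deposited log2 level of every probe set of Gata1 to Gata6 on each array, with points for arrays and bars for mean ± SD. At both Gata5 probe sets the 3 KO arrays lie below the 4 WT arrays, with means of 4.95 against 5.54 at 1450126_at.

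The comparison of KO with WT lungs asked which transcripts change when Gata5 is deleted. The largest increase was in Cirbp, a cold-inducible RNA-binding protein, which rose 2.68-fold, from 6.15 ± 0.24 (SD, n = 4) to 7.57 ± 0.22 (SD, n = 3; limma adjusted p = 0.00526). Gp1bb, a subunit of the platelet receptor for von Willebrand factor, rose 2.03-fold, Tlr1, a receptor for bacterial lipopeptides, 1.95-fold, Cd163l1 1.98-fold and Adgrg2, an adhesion G protein-coupled receptor, 1.87-fold. D830026I12Rik (1.95-fold), Zc3h6 (1.90-fold), Srpk3 (1.88-fold), Caps2 (1.86-fold) and Acap1 (1.83-fold) completed the 10 largest increases. The decreases were larger. Upk3b, a uroplakin made by mesothelium, fell 3.76-fold, from 8.41 ± 0.67 to 6.50 ± 0.68 (adjusted p = 0.0191), and Apoe, the lipid-carrying apolipoprotein E, fell 3.08-fold, from 7.99 ± 0.21 to 6.37 ± 0.49 (adjusted p = 0.00648). Stip1, a co-chaperone that links the Hsp70 and Hsp90 chaperones, fell 2.84-fold, from 7.34 ± 0.11 to 5.83 ± 0.31 (adjusted p = 0.00486). Hspa1b (3.38-fold), Hspa1a (3.10-fold) and Hsph1 (2.56-fold), all heat-shock chaperones, Rabac1 (2.89-fold), Gnb2, a G protein beta subunit (2.84-fold), Bsg, the cell-surface glycoprotein basigin (2.49-fold), and Csrp1 (2.45-fold) were the others. The other probe set of Csrp1, which lies under the level filter, had a log2 change of 0.09. In each of these 20 genes the 3 KO arrays and the 4 WT arrays did not overlap, as the rule for naming them required.

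Over all 13285 genes tested, 2069 changed (15.6%), 738 higher and 1331 lower in KO, with a median change of 1.31-fold. A change of at least 2-fold was seen in 31 of them, 2 higher and 29 lower. At unadjusted p under 0.01 and at least 1.5-fold there were 328 genes, 67 higher and 261 lower. Groups did not overlap for 29.6% of genes, against 5.71% by chance. The balance of directions moved with the scaling: 35.7% of changed genes were higher in the deposited values, 57.1% of 2096 after a further quantile normalization, 24.6% of 2218 after centring each array on its median and 46.8% of 2018 after cyclic loess, an alternative chosen after the data were seen. The count fell to 891 without WT replicate 4, 1017 without WT replicate 1 and 1104 without either KO replicate 3 or WT replicate 3. It was 0 with limma when the beta-actin 3′ to 5′ difference was a covariate, with 2204 genes at unadjusted p under 0.05, 0 with the beta-actin 3′ to middle difference (1742) or the hybridisation spikes (1836), 5 with the Gapdh difference (2726), and 0 with limma among the 5 mice with the lowest mouse numbers alone, with 2791. Of 87 genes named in the text that passed, 42 also passed whichever array was left out. Among the 20 largest changes, Acap1, Caps2, Cd163l1, Hspa1a, Rabac1, Tlr1 and Upk3b each lost the call when 1 of 3 or more arrays was left out, with the highest adjusted p at 0.0582, 0.0784, 0.0826, 0.0740, 0.0616, 0.0815 and 0.0676 in that order.

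**Figure D3:**
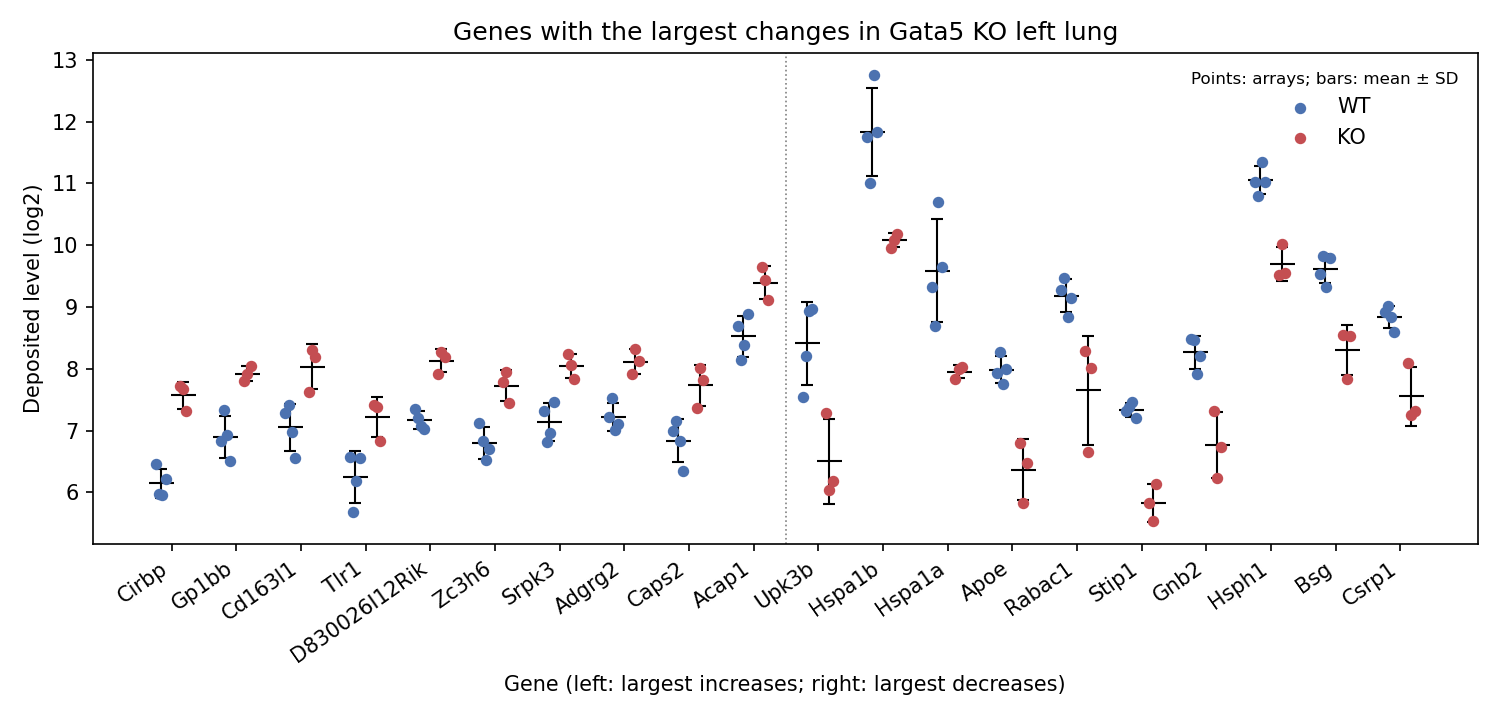
Deposited log2 level of the 10 largest increases (left) and 10 largest decreases (right) on each array, with points for arrays and bars for mean ± SD. Cirbp lies at 7.57 in KO against 6.15 in WT, and Upk3b at 6.50 against 8.41.

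Direction varied with the level of a gene. In the dimmest of 10 bins of tested genes, 71.6% of the changed genes were higher in KO, with a median log2 change of 0.11 over all genes of the bin, whereas in the brightest bin 29.0% were higher, with a median of -0.04. Changed genes without a protein product were mostly higher: 74 of 81 (91.4%), against 661 of 1985 protein-coding genes (33.3%, odds ratio 21.1, 95% interval 9.69 to 54.6, Fisher's exact p = 1.10e-26). The test counts genes as independent, although genes on the same arrays can move together, so its interval and p do not measure the spread between mice. Over all 533 tested genes without a protein product the median log2 change was 0.13, against -0.01 for protein-coding genes. Under a further quantile normalization, median centring and cyclic loess these shares were 93.2%, 85.5% and 85.9% for non-coding genes and 55.4%, 22.6% and 45.3% for coding genes.

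**Figure D4:**
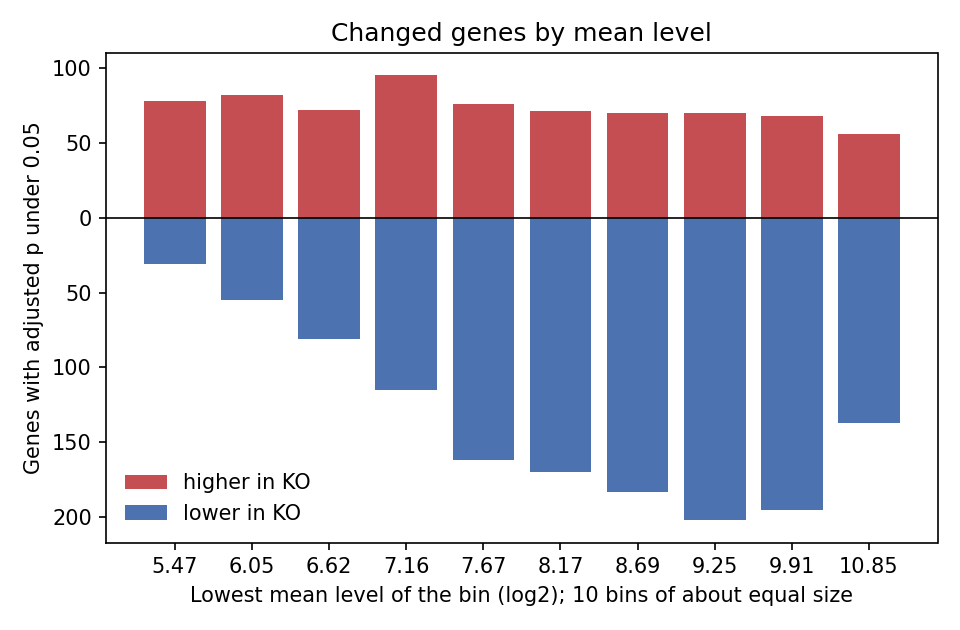
Number of changed genes in 10 bins of mean log2 level, higher in KO above the line and lower in KO under it. The dimmest bin holds 78 higher and 31 lower genes, and the brightest 56 higher and 137 lower.

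Several genes of protein folding fell in KO lungs. Of 20 tested genes of the heat shock and unfolded protein list, 12 fell, 0 rose and 8 did not pass, and 14 fell when adjusted over the list alone. Beside Hspa1b, which went from 11.84 ± 0.72 (SD, n = 4) to 10.08 ± 0.12 (SD, n = 3), and Hsph1, from 11.05 ± 0.23 to 9.70 ± 0.28, the changed members included chaperones of the endoplasmic reticulum: Pdia6, a disulfide isomerase, fell 1.70-fold, Hspa5, the chaperone BiP, 1.62-fold and Hsp90b1 1.42-fold. Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain, and the call of Hspa1a was lost without any one of KO replicates 1 to 3, WT replicate 1 or WT replicate 4 (adjusted p up to 0.0740). The list's median log2 change was -0.43 (camera adjusted p = 1.35e-06), and the call was lost in the stricter test (adjusted p = 0.826 with an estimated correlation). Of the 2 other probe sets of Hspa5, 1 had a log2 change of -1.05 and 1 of 0.18, and the other probe set of Pdia6, under the level filter, one of 0.14. The same KO arrays had the larger 3′ to 5′ differences of the controls, 4.96 against 4.10 for beta-actin.

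Some markers of vessel lining, smooth muscle and alveolar type 2 cells fell, and more than that number in each list did not pass. In the endothelial list 7 of 17 tested genes fell and 10 did not pass, with 9 lower when adjusted over the list alone. Pecam1, an adhesion molecule at endothelial junctions, fell 2.33-fold, from 8.57 ± 0.24 (SD, n = 4) to 7.36 ± 0.30 (SD, n = 3), Tie1, an endothelial receptor kinase, 1.78-fold, Nos3, the endothelial nitric oxide synthase, 1.52-fold and Flt1, a receptor of vascular endothelial growth factor, 1.38-fold. Of 15 smooth muscle genes 6 fell, 1 rose and 8 did not pass, with the same counts of 6 and 1 adjusted over the list alone. Myl9, a myosin light chain, fell 1.56-fold, and the actin-binding Tagln 1.49-fold. Hhip, a hedgehog-binding protein, and Des, the intermediate filament desmin, fell with log2 changes of -0.59 and -0.58, while Tpm2, a tropomyosin, rose with a log2 change of 0.33. Of 14 type 2 cell genes 4 fell and 10 did not pass, with 6 lower adjusted over the list alone. These were the mucin Muc1 (1.74-fold), the complement component Hc (1.41-fold), the transcription factor Etv5 (1.40-fold) and Lpcat1, an enzyme of surfactant lipid synthesis (1.30-fold). The surfactant protein genes Sftpc and Sftpb did not pass, with log2 changes of -0.12 and -0.74, and the sign was opposite under 1 alternative for Sftpc and under 3 for Sftpb. Sftpb was at -0.39 without KO replicate 2 (adjusted p = 0.0383) and -0.97 without KO replicate 1 (adjusted p = 0.0365). Probe sets of 1 gene differed in sign: 1 of the 3 others of Flt1 had a log2 change of 0.27, 1 of the 3 others of Hhip 0.01, 2 of the 4 others of Lpcat1 0.06 and 0.22, and 1 of the 2 others of Etv5 0.07. Camera adjusted p was 0.00147 for endothelial, 0.0144 for smooth muscle and 0.00317 for type 2 genes, and each call was lost, at adjusted p = 0.826 with an estimated correlation. The type 2 call was also lost with the beta-actin 3′ minus 5′ difference as covariate (median log2 change -0.21 against -0.22, adjusted p = 0.272). With that covariate a median of 82.6% of the type 2, 96.3% of the endothelial and 114% of the smooth muscle change was kept, but with the beta-actin 3′ minus middle difference 23.0%, 37.0% and 96.5%, when the type 2 and endothelial calls were lost (medians -0.013 and -0.091 against -0.22 and -0.27, adjusted p = 0.566 for both). With the Gapdh difference 142%, 109% and 128% was kept, and each list passed. With the hybridisation spikes as covariate the type 2 and smooth muscle calls were lost (adjusted p = 0.183 and 0.0787), with medians of -0.21 against -0.22 and -0.29 against -0.28. The smooth muscle call was lost with the mean of all probe sets of a gene (median -0.25, adjusted p = 0.0589), as were the calls of Nos3 and Hc without KO replicate 3 (adjusted p = 0.0588 and 0.0616), of Des without WT replicate 1 or 4 (up to 0.0592), of Etv5 when any of KO replicates 1 to 3 or WT replicates 3 and 4 was left out (up to 0.0966), and of Tpm2 when any array but KO replicate 1 was left out (up to 0.109).

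**Figure D5:**
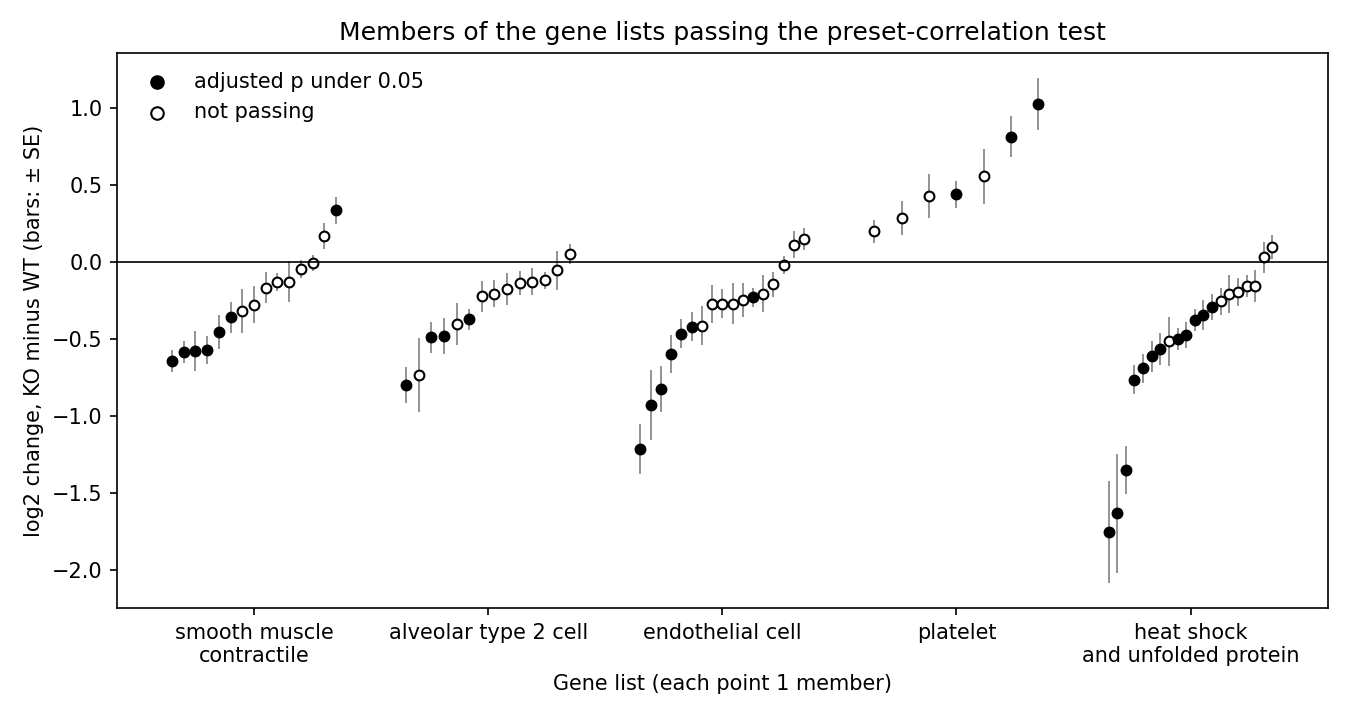
Log2 change, KO minus WT, of each tested member of the 5 lists that passed the test with a preset correlation, with bars for ± SE and filled points for members with adjusted p under 0.05. Platelet members lie above 0, and most members of the other 4 lists lie under it.

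Of 7 tested platelet genes, 3 rose in KO lungs and 4 did not pass, whereas 7 were higher when adjusted over the list alone. Gp1bb went from 6.90 ± 0.34 (SD, n = 4) to 7.92 ± 0.12 (SD, n = 3), the platelet chemokine Ppbp rose 1.75-fold, from 10.20 ± 0.21 to 11.01 ± 0.22, and the platelet receptor Treml1 rose 1.35-fold. Pf4, platelet factor 4, had a log2 change of 0.55 and did not pass (adjusted p = 0.0677). The list's median log2 change was 0.44 (camera adjusted p = 0.000885, but adjusted p = 0.826 with an estimated correlation). That median was 0.72 with the beta-actin 3′ minus 5′ difference as covariate (165% of the members' change kept), 0.68 with the hybridisation spikes, 0.64 with the Gapdh difference (123%) and 0.35 with the beta-actin 3′ minus middle difference (59.5%), when the call was lost (adjusted p = 0.122). Treml1 lost its call without KO replicate 3 (adjusted p = 0.0526). Of 3 tested erythroid genes, none passed (camera adjusted p = 0.822). Over all lists, 5 passed with the preset correlation and 0 with an estimated one, and 31 of the 35 splits of the arrays passed at least 5 lists. Fry passed 3 lists at adjusted p = 0.0218: heat shock, smooth muscle and the Bmal1-phase clock list, in which Clock, of 3 tested genes, fell (log2 change -0.57).

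The remaining lists did not pass. Of 6 mesothelial genes 3 fell: Upk3b, Lrrn4 (log2 change -1.15) and Msln (-0.93; camera adjusted p = 0.0735). Among 20 matrix and fibroblast genes, 4 fell, with Fn1, fibronectin, at -0.85 and Dcn, decorin, at -0.46, and Col5a1 rose by 0.22 (adjusted p = 0.0968). Type 1 cell genes included 2 of 14 lower, Cldn18, a tight-junction claudin, at -0.95 and Igfbp2 at -0.50 (adjusted p = 0.492). Ager and Hopx, the brightest of that list, did not pass at the probe sets used (-0.02 and -0.09), but their other probe sets were at -0.62 and -0.53. Of 14 nitric oxide and endothelin genes, Nos3, also in the endothelial list, and Ddah2 (-0.44) fell (adjusted p = 0.168), and of 17 receptors and signalling genes of airway tone, Pde4b (-0.60) fell and Ptger1 (0.21) rose (adjusted p = 0.904). Tppp3 (-0.71) and Hydin (0.33) were the changed genes among 20 of ciliated cells (adjusted p = 0.142). Among 13 lipid transport genes, Apoe, Lrp1 (-0.52) and Apoc1 (-0.33) fell and Apoa5 (0.27) and Apoc4 (0.26) rose (adjusted p = 0.822). Sc5d (-0.83) fell among 17 cholesterol genes (adjusted p = 0.492), Angptl4 (-0.78), Hadha (-0.30) and Acadvl (-0.27) fell and Srebf1 (0.23) rose among 21 of fatty acid metabolism (adjusted p = 0.614), and Sdhc (-0.69), Atp5b (-0.59), Uqcrc1 (-0.43) and Cox4i1 (-0.30) fell among 29 of the respiratory chain (adjusted p = 0.614). Mcm5 (0.39) rose and Ube2c (-0.64) and Pcna (-0.36) fell among 22 cell cycle genes (adjusted p = 0.822). Bst2 (-0.54) and Stat2 (-0.36) fell among 19 interferon genes (adjusted p = 0.855), Tsc22d3 (-0.83) and Angptl4 among 12 glucocorticoid-responsive genes (adjusted p = 0.0968), Btg2 (-0.31) among 13 immediate early genes (adjusted p = 0.904) and Cebpa (-0.59) among 6 endoderm transcription factors (adjusted p = 0.904). No member passed in the club cell, goblet cell, alveolar macrophage, neutrophil, type 2 inflammation, mast cell, B and plasma cell, T and NK cell, adipose, cardiac, skeletal muscle, Dbp-phase clock, xenobiotic, large airway, thymus, nerve or sex-linked lists. A list for cartilage had too few tested members for a test. Of the changed genes named from these lists, Fn1, Cldn18, Tppp3, Lrp1, Apoe, Sc5d, Sdhc, Atp5b, Mcm5 and Bst2 passed whichever array was left out. Each of the others lost its call without at least 1 array, including Dcn and Igfbp2 without KO replicate 3 (adjusted p = 0.0555 and 0.0794), Cox4i1 without WT replicate 1 (0.0516), Btg2 and Ddah2 without WT replicate 1 or 4 (up to 0.0542 and 0.0678), and Apoc4 and Ptger1 without any one of the 7 arrays (up to 0.115 and 0.117), and Cebpa turned to 0.055 with the beta-actin difference as covariate.

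The genes that lie next to Gata5 on its chromosome were compared with the rest, since a targeted allele can carry flanking sequence of another strain. Of 75 tested neighbours 12 changed (16%), against 2057 of 13210 other genes (15.6%; odds ratio 1.03, 95% interval 0.506 to 1.94, Fisher's exact p = 0.874). The nearest changed neighbours were Mrgbp (log2 change 0.22), Dido1 (-0.25), Taf4, a subunit of the general transcription factor TFIID (-0.36), Nkain4 (-0.43) and the collagen gene Col20a1, which rose 1.62-fold (adjusted p = 0.0122). At unadjusted p under 0.01 the counts were 14 of 75 and 2312 of 13210 (odds ratio 1.08, Fisher's exact p = 0.761). Another probe set of Dido1 had a log2 change of 0.29, and that of Mrgbp, under the level filter, one of -0.02. The calls of Mrgbp and Dido1 were lost whichever of the 7 arrays was left out (adjusted p up to 0.109 and 0.121), that of Nkain4 when any of KO replicates 1 to 3 or WT replicates 3 and 4 was left out (up to 0.105), and that of Taf4 without WT replicate 3 or 4 (up to 0.0574).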

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

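The tests of the array splits for both counts of genes, of other probe sets going the opposite way and of probe sets with no gene given, the control indices as covariates in limma and camera, and cyclic loess were chosen only after the results were seen.

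On several genes and lists 1 WT array stood far from the others, measured as its gap to the nearest array over the range of the 4. The gap share was 0.903 for Hc (WT replicate 4 at 12.55, others 12.24 to 12.27), 0.882 for Inmt (WT replicate 4 at 13.58, others 13.41 to 13.43) 0.961 for Alas2 (WT replicate 2 at 10.81, others 9.78 to 9.82) and 0.930 for Igfbp2 (WT replicate 2 at 9.85, others 9.42 to 9.45). For sex-linked genes, with WT replicate 4 apart, it was 0.980 for Xist (at its brightest probe set, 12.72 against 6.31 to 6.44), 0.986 for Eif2s3y, 0.991 for Kdm5d and 0.954 for Uty, and 0.958 for their list. The immediate early list gave 0.852 (WT replicate 3) and the thymus list 0.939 (WT replicate 4). Of 178 items tested 11 stood out (6.18%), 6 of them not sex-linked, and chance marks about 1 in 20 groups. The KO group of 3 was not tested in this way. Without WT replicate 4 a median of 96.7% of the changed genes' log2 change was kept. These genes had been called with that array included, so a high share was likely whatever the cause. Among the remaining arrays, which had like sex-linked levels, 891 genes passed, 880 of them also changed in all arrays. Those calls do not rest on the sex of WT replicate 4, and for the other changed genes this stays open.

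In control probe sets that no comparison of genes used, KO exceeded WT by a log2 difference of 0.86 in the beta-actin 3′ minus 5′ difference, 0.55 in the Gapdh 3′ minus middle difference and 0.29 in the hybridisation spikes (10.86 ± 0.11 against 10.57 ± 0.08). With the spike level as a covariate a median of 96.0% of the log2 change was kept (88.3 to 112 over both spike indices and leaving out each array), but 0 genes passed in limma, with 1836 at unadjusted p under 0.05 (0 and 1864 without the cre spike), as the median standard error went from 0.08 to 0.17. More than 75% kept had been set beforehand as arguing against the amount of sample signal and was met. The slope came from within the groups, which did not overlap in the spike level, so the share kept does not decide this cause.

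The first pattern weighed was the number of changed genes: 2069 passed against a highest count of 0 in the other splits. At the second threshold 328 passed against 102, so that 1 of 35 splits gave as many in each case. This is the smallest share that 35 splits can give, and the test was chosen after the counts were seen, so chance is less likely but not excluded. Any other difference between the KO and WT arrays, such as that in the control probe sets, would give the same share. After cyclic loess a median of 91.5% of the log2 change was kept, which argues against a level-dependent shift as the whole cause. With higher and lower genes taken apart, the smaller of the medians was 88.0% and the larger 108%. With the beta-actin difference as a covariate the median kept was 98.3% (75.8 to 111 over 3 indices and leaving out each array), but 0 genes passed in limma, with 2204 at unadjusted p under 0.05 (0 and 1742 for beta-actin 3′ minus middle, 5 and 2726 for Gapdh, while 290, 310 and 408 passed the second threshold), because the median standard error went from 0.08 to 0.16 while the median absolute log2 change went from 0.38 (quartiles 0.31 and 0.50) to 0.37 (quartiles 0.25 and 0.52). More than 75% kept for each index had been set beforehand as arguing against RNA integrity. This bound was met (81.2% for beta-actin 3′ minus middle, 104% for Gapdh). Simulated genes kept 1.47% when driven by the beta-actin 3′ minus 5′ index and 101% when driven by the group, but there the index was known without error. On the arrays, beta-actin 3′ minus 5′ correlated within groups at -0.11 with beta-actin 3′ minus middle and 0.72 with Gapdh. The correlation of beta-actin 3′ minus middle with Gapdh was -0.41. The covariate slope came from within the groups, no index overlapped between them, and 1 of the 3 ranked the KO arrays differently. Indices that track RNA integrity loosely can leave a high share kept even if it was the whole cause, so these shares do not decide it. Of 1678 other probe sets of changed genes, only 1060 (63.2%) had the same sign as the probe set that was called. At unadjusted p under 0.05 in limma, 600 went the same way and 205 (12.2%) the opposite way. Chance gives 2.5% for the opposite way in an unchanged probe set. However, 9575 of 27023 probe sets tested singly were at unadjusted p under 0.05 in limma, so 2.5% is too low a baseline here. The share of 12.2% therefore does not decide whether part of the pattern concerns parts of transcripts, through probe position, 3′ bias or isoforms. The 3′ to 5′ differences of the controls were larger on the KO arrays. An effect of the Gata5 deletion stays open.

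The second pattern was the lower heat shock and unfolded protein list, set beside the higher Cirbp. Chance cannot be excluded for the number of lists that passed, since 31 of 35 splits passed at least as many as the real 5 and the highest other passed 16. Of 18 heat-shock genes outside the list, 11 fell (61.1%, 95% interval 35.7 to 82.7), among them Hspa4l at -0.86, Hspd1 at -0.71 and Bag3 at -0.65. The interval counts genes as independent and does not measure the spread between mice. Camera on these 18 genes, without a covariate, gave unadjusted p = 8.36e-08 at the preset correlation and 0.0243 with an estimated one. A lower heat-shock programme in the KO lungs could give these values, and so could temperature or handling at collection. With the beta-actin 3′ minus 5′, beta-actin 3′ minus middle and Gapdh differences as covariates a median of 132%, 92.7% and 145% of the members' change was kept (57.1 to 157 with arrays left out), and the list passed camera in each case, with medians from -0.64 to -0.32 and adjusted p up to 0.00213. These shares have the same limit as those of the first pattern and do not decide whether RNA integrity was the cause. In addition, 57.1 (without KO replicate 1) lies under the 75% set beforehand. With these covariates no camera call of the fixed list held with an estimated correlation (adjusted p from 0.443). RNA integrity therefore stays open as a cause of the lower list.

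The third pattern was that 91.4% of changed non-coding genes were higher. The odds ratio of 21.1 fell to 13.9 (95% interval 6.28 to 36.5) within bins of level and to 7.36 (3.71 to 16.2) after cyclic loess. What remained argues against a level-dependent shift as the whole cause, but the fall leaves it open as a part of the cause. Changed probe sets with no gene given were also more often higher, 320 of 522 (61.3%) against 1243 of 3809 with 1 gene (32.6%, odds ratio 3.27, 95% interval 2.70 to 3.97). This comparison was made without the level filter and without bins of level. Since 71.6% of changed genes in the dimmest bin of tested genes were higher, it does not separate the lack of a gene from a low level. All of these intervals count genes or probe sets as independent and do not measure the spread between mice. A larger share of non-coding or unspliced RNA in the KO samples is a candidate explanation, and whether it would come from the lungs or from RNA handling was not tested.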

How the results depend on the processing

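The covariates from control probe sets and cyclic loess, and median centring for the lists, were chosen only after the results were seen. The number of arrays, and signal near background for dim genes such as Gata5, limits what follows. Of 87 named genes that passed, 86 kept their direction in every alternative run on single genes, which leaves out probe sets tested singly; Cebpa became 0.055 with the beta-actin covariate. Leaving out 1 array ended the call of 45 of them. The directions of the 5 passing lists held under each scaling.

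The 2069 changed genes became 4729 with all 27023 probe sets tested singly, 902 with Xist as a covariate (890 shared), 0 with the beta-actin covariate (limma; 2204 at unadjusted p under 0.05), 0 with beta-actin 3′ to middle (1742), 5 with Gapdh (2726), 0 with the hybridisation spikes (1836), 0 for the 5 mice with the lowest mouse numbers alone (limma; 2791 at unadjusted p under 0.05), and 891 to 1951 when 1 array was left out. The 328 genes at the second threshold became 998 with probe sets singly and 200 with the mean of a gene's probe sets. More probe sets than genes were tested singly, and fewer arrays were used for the 5 mice and when 1 was left out. With the beta-actin covariate the median standard error went from 0.08 to 0.16, and with the others to 0.15, 0.14 and 0.17. The Xist covariate mainly set WT replicate 4 (11.51) apart from the other arrays (3.66 to 3.89), and its count of 902 was close to the 891 without that array. For the mean of probe sets the cause was not tested. Replicate numbers did not pair the arrays: across genes, deviations of same-numbered arrays correlated at 0.003, -0.04 and 0.04, and not every array correlated best with its own number. With the replicate block 371 genes passed (351 shared) and 11 lists.

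Gata5 at 1450125_at passed after a further quantile normalization (-0.34, adjusted p = 0.0419), and 1450126_at ranged from -0.70 to -0.48 when 1 array was left out. The 5 passing lists became 0 with an estimated correlation, 3 with fry, 9 without the level filter and 6 to 9 when 1 array was left out. The odds ratio for neighbours of Gata5 was 0.756 and 1.02 in 2 smaller sets of neighbours, 0.941 without the level filter and 0.754 to 1.65 when 1 array was left out, and none of these passed. The cause was not tested.

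Genes that had not passed changed sign as follows, and the cause was not tested. With cyclic loess: Actc1 0.012, Ager 0.041, Ccr9 -0.010, Gata4 -0.0055, Gpm6a 0.026 and Mbp 0.058. With quantile normalization: Actc1 0.0077, Ager 0.0096, Cox8b 0.0085, Gpm6a 0.055 and Mbp 0.079. With those 5 mice alone: Ager 0.015, Gata2 -0.01, Gpm6a 0.15, Hdc -0.03, Jchain -0.37, Mbp 0.055, Muc5b -0.17, S100a8 -0.23 and Slc4a1 -0.33. With the beta-actin covariate: Ccl5 -0.23, Ckm 0.056, Gpm6a 0.12, Sftpb 0.29, S100a8 -0.70 and Slc4a1 -0.44. With beta-actin 3′ to middle: Ager 0.093, Chil3 0.12, Col1a2 0.15, Cyp2f2 -0.11, Dynlrb2 -0.13, Gata3 0.024, Gata6 0.20, Gpm6a 0.21, Hdc -0.055, Hopx 0.051, Jchain -0.66, Kit 0.13, Krt5 -0.056, Mbp 0.29, Mrc1 0.11, Muc5b -0.62, S100a9 1.31, Scgb1a1 -0.013, Slc4a1 -0.90 and Upk1b 0.58. With Gapdh: Ckm 0.095, Krt4 -0.021, Sftpb 0.14 and Slc4a1 -0.077. With the hybridisation spikes: Actc1 0.035, Alas2 0.36, Ckm 0.25, Col1a2 0.087, Gata2 -0.031, Gpm6a 0.26, Mbp 0.042, S100a8 -0.26, Sftpb 0.19, Slc4a1 -0.43 and Tff2 -0.020. With the mean of probe sets: Col1a2 0.10, Cryab -0.020, Hdc -0.18, Mbp 0.27 and Sftpc 0.25. Without probe sets of shared sequence: Ighm -0.22, Mbp 0.30 and Slc4a1 -0.061. With array weights: Mbp 0.017 and Slc4a1 -0.053. With the replicate block: Jchain -0.20, Mbp 0.027 and Slc4a1 -0.087. With Xist as covariate: Jchain -0.20, Mbp 0.026 and Slc4a1 -0.092. With median centring: Gata2 -0.019. Leaving out 1 array gave ranges of -0.22 to 0.12 for Actc1, -0.0425 to 0.0125 for Ager, -0.01 to 0.70 for Ccl5, -0.03 to 0.15 for Ccr9, -0.18 to 0.077 for Ckm, -0.22 to 0.17 for Cox8b, -0.0575 to 0.07 for Gata2, -0.15 to 0.05 for Gpm6a, -0.20 to 0.43 for Jchain, -0.0525 to 0.0725 for Mbp, -0.105 to 0.215 for Muc5b, -0.16 to 0.57 for S100a8, -0.455 to 0.54 for S100a9 and -0.16 to 0.56 for Slc4a1.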

Other observations

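The test of erythroid genes was chosen only after the result was seen, and the platelet and heat-shock genes outside the lists were drawn up after those lists' results and before their own values were seen.

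Beyond the fixed platelet list, Clec1b, a receptor that activates platelets, rose 1.51-fold in KO lungs (limma adjusted p = 0.0292), and Nfe2, a transcription factor of megakaryocytes, rose 1.34-fold (adjusted p = 0.0415). The Clec1b call was lost when any array but KO replicate 1 or WT replicate 2 was left out (adjusted p up to 0.0936) and the Nfe2 call when any but KO replicate 3 was (up to 0.110). Rgs18 and Selp, the adhesion molecule P-selectin, had log2 changes of 0.46 and 0.49 and did not pass. Among heat-shock genes outside the fixed list, Cacybp (1.72-fold lower), Fkbp4 (1.56-fold lower), which binds Hsp90, and the small heat-shock protein Hspb8 (1.62-fold lower) also fell, while Cryab, another small heat-shock protein, had a log2 change of 0.16 and did not pass.

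A hypothesis for the platelet list is that the KO lungs held more platelet or megakaryocyte RNA. Of 13 platelet and megakaryocyte genes outside the list 2 rose (15.4%, 95% interval 1.92 to 45.4). That interval is too wide to decide the hypothesis, and it counts genes as independent, so it does not measure the spread between mice. More residual blood may be another source, and the 3 tested erythroid genes had a median log2 change of 0.13 (range -0.29 to 0.17), which does not decide it either, since Slc4a1 and Alas2 varied between arrays by more than this.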
